A study of Homo sapiens with 3 samples.

How the data were processed

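RNA was sequenced from 3 HGC-27 libraries, 1 shControl and 2 labelled shUSP16, grouped by their titles. The deposited table gave FPKM values (fragments per kilobase scaled to library size) for 58735 genes with 1 column per library, per the file headers, together with gene length, coordinates and biotype. The aligner, counting tool, strand setting, read length and RNA selection are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, but all 58735 gene IDs and their coordinates equal those of the human GENCODE release 29 annotation on GRCh38, so coordinates are given on GRCh38. The labels' protocols also describe a hormone treatment with dexamethasone, isobutylmethylxanthine and insulin for all 3 libraries; whether these cells received it is unclear. Gene length is the value the authors deposited per gene, in bases.

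The product of FPKM and gene length was a whole multiple of a fixed step in each library for 100% of values above 0, with a tolerance of 0.01 reads, so whole reads could be recovered. They summed to 30131136 in shControl, 29530581 in shUSP16-1 and 31187845 in shUSP16-2. The totals implied by the authors' FPKM were 1.08, 1.01 and 0.994 times those sums, so a further scaling factor per library had been applied by a method not given in the sources used here. This lowers the deposited values of shControl relative to scaling by sums of reads, so both scalings were compared. Between the 2 libraries labelled shUSP16, chi-square per degree of freedom was 13.1 over 18422 genes, so they were not one library deposited again and were entered as 2 libraries; this does not show that they came from separate cultures.

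Values were analysed as log2(FPKM + 1), so fold changes understate the change of low genes, over the 13852 genes with a mean of at least 1 FPKM. limma 3.58.1 in R 4.3.3 compared the groups with moderated variances and a mean trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread came from the 2 libraries labelled shUSP16 alone, with 1 residual degree of freedom per gene and a prior of 4.05 degrees of freedom, and the lone control was assumed to vary like them. A rule of size with no test counted genes at least 2-fold from shControl in both libraries labelled shUSP16. The correlation of fold changes and this count were set beside 100 simulations of unchanged libraries sharing a control, with noise taken from the difference between the libraries labelled shUSP16. An exact permutation test cannot reach a p of 0.05 with 3 libraries.

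Gene lists were tested with camera at a preset correlation of 0.01, for the 26 of 30 lists with at least 5 tested members, and each median was ranked among 10000 random lists matched on mean expression. The lists, tests, rule for named genes and most alternatives were fixed before the data were examined. Adjusting limma p-values over the members of a list alone was not part of that plan. It does not account for the other genes and lists. Named genes were USP16; up to 12 protein-coding genes per direction with the largest change of the weaker library, taken from limma calls if at least 12 were called and otherwise from genes past 2-fold in both; up to 4 members per list by the same measure; and CDKN1A, MYC, CDKN2A, CCNB1, PLK1, MKI67, VIM, CDH1 and RPS27A. Genes named outside this rule are said to be chosen after their values were seen.

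limma, voom and camera were tested on 20 simulated data sets of this design with 200 changed genes among 13852. The sign was right for 98.0% or more of the changed genes, and camera found a list shifted by 0.4 in 19 of 20 simulations and called 1 of 500 other lists. Simulated genes varied independently of each other. The 1 of 500 therefore does not show how often camera calls unchanged lists whose members vary together. Alternatives were the pseudocount (0.1), filters on low values (none, or a mean of at least 5 FPKM), scaling to equal totals or by median ratio, protein-coding genes only, no trend or a robust trend, an estimated correlation in camera, fold thresholds of 1.5 and 3, an adjusted p of 0.1 and leaving out each library labelled shUSP16. Added after seeing the data were limma voom on recovered reads with either kind of total, camera on those values and on protein-coding genes, and each library labelled shUSP16 as the lone library. Intervals of ratios of reads are exact binomial 95% intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.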

Results

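RNA-seq expression was measured in HGC-27, an established human gastric cancer cell line, carrying a control short hairpin RNA (shControl) or a hairpin against USP16 (shUSP16). USP16 is a deubiquitinase best known for removing ubiquitin from lysine K119 of histone H2A. There was 1 shControl library and there were 2 libraries labelled shUSP16, named shUSP16-1 and shUSP16-2. The labels do not say whether the numbers mark different hairpins or repeats, or whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The reads recovered from the deposited FPKM values came to 30131136 for shControl, 29530581 for shUSP16-1 and 31187845 for shUSP16-2. With 1 control library, every difference below is a difference from that library.

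USP16 mRNA was lower than in shControl in the library labelled shUSP16-1 and close to it in the library labelled shUSP16-2. USP16 (ENSG00000156256, chromosome 21, 29024629 to 29054488, plus strand, GRCh38) had 6.28 FPKM from 1165 reads in shControl, 4.29 FPKM from 730 reads in shUSP16-1 and 5.98 FPKM from 1056 reads in shUSP16-2. The ratio to shControl was 0.683 in shUSP16-1 (exact binomial 95% interval 0.621 to 0.749) and 0.952 in shUSP16-2 (0.875 to 1.04); intervals cover counting error only. Scaled by the sums of reads, the ratios were 0.639 (0.582 to 0.702) and 0.876 (0.805 to 0.953). Among the 13852 genes tested, 6.30% were as low or lower relative to shControl in shUSP16-1 and 35.6% in shUSP16-2. In limma, USP16 differed by a log2 value of -0.26 with an SE of 0.20 and did not pass (adjusted p = 0.564). Since the targeted gene was barely lower in shUSP16-2, both are called libraries labelled shUSP16, and each direction below rests on those labels. USP16 mRNA backs the label of shUSP16-1 beyond counting error with both scalings, and that of shUSP16-2 only with sums of reads.

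**Figure D1:**
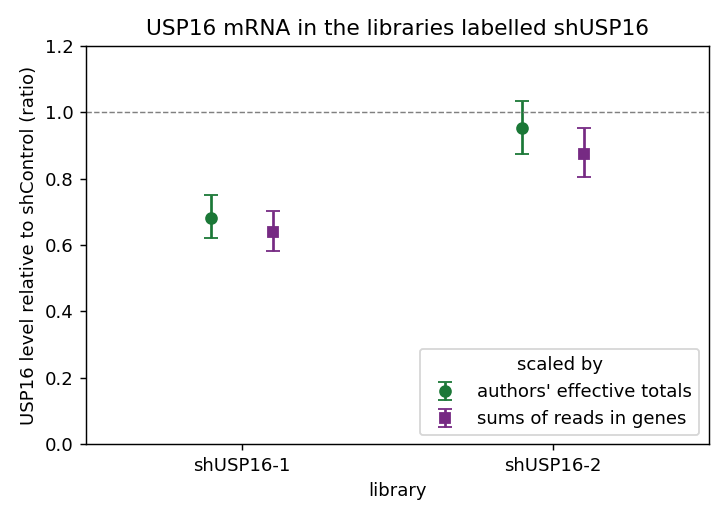
USP16 level relative to shControl (vertical axis, ratio) in the 2 libraries labelled shUSP16 (horizontal axis); circles use the effective totals behind the authors' FPKM, squares the sums of reads, and bars are exact binomial 95% intervals. With the authors' totals, shUSP16-1 lies at 0.683 and shUSP16-2 at 0.952, whose interval includes 1.

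The comparison of shUSP16 with shControl asks which genes differ when USP16 is targeted. Among protein-coding genes the lowest in both libraries labelled shUSP16 included NDUFA4L2, a mitochondrial protein gene induced in hypoxia, and CA9, a carbonic anhydrase induced in hypoxia. NDUFA4L2 (ENSG00000185633, chromosome 12, 57234903 to 57240715, minus strand) was at 42.8 FPKM in shControl and 10.3 ± 1.45 (SD, n = 2) in shUSP16, a log2 difference of -1.96. CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159, plus strand) was at 10.3 FPKM in shControl and 2.79 ± 0.373 (SD, n = 2) in shUSP16. JUN, an AP-1 transcription factor gene (ENSG00000177606, chromosome 1, 58780788 to 58784327, minus strand), was at 166 FPKM in shControl and 67.5 ± 3.64 (SD, n = 2) in shUSP16, with a log2 difference of -1.29. MT2A, a metallothionein that binds metal ions (ENSG00000125148, chromosome 16, 56608199 to 56609497, plus strand), was higher, at 98.9 FPKM in shControl and 219 ± 3.99 (SD, n = 2) in shUSP16.

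None of these passed the test fixed for all genes. limma with a variance trend called 0 of 13852 genes, with 2008 at an unadjusted p under 0.05 and a lowest adjusted p of 0.164, which NDUFA4L2, CA9, JUN and MT2A shared. On simulated data of this design limma called 2.60% of genes made 4-fold lower, 6.90% of genes made 4-fold higher and 1 of 1000 genes made 2-fold higher, so the count of 0 had little power behind it. It also made a mean of 1.55 false calls per simulation. limma restricted to 11069 protein-coding genes, an alternative fixed before the data were examined, called 48 genes, 17 higher and 31 lower. This restricted fit was not run on the simulated data, so its rate of false calls is not known. There NDUFA4L2 (adjusted p = 0.000547), CA9 (adjusted p = 0.00122), JUN (adjusted p = 0.00185) and MT2A (adjusted p = 0.00225) were called. limma voom on recovered reads, an alternative added after seeing the data, called 348 genes, 204 higher and 144 lower, with 44 of the 48 among them. With sums of reads as totals it called 557, 139 higher and 418 lower, so the split between higher and lower depended on the scaling. Voom called 74.7% of genes simulated 4-fold higher and 28.2% of those simulated 2-fold higher, with a mean of 10.4 false calls per simulation.

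By size alone, 79 genes were at least 2-fold from shControl in both libraries labelled shUSP16, 19 higher and 60 lower. Of these, 13 were protein-coding, 4 higher and 9 lower. Besides NDUFA4L2, CA9 and JUN, the lower genes were CXorf49, AC004556.1, U2AF1, PLEKHH2, TBC1D3D and EGR3. EGR3, an immediate early transcription factor gene, had 9.57 FPKM in shControl and 3.56 ± 0.994 (SD, n = 2) in shUSP16. PLEKHH2 had 6.86 FPKM in shControl and 2.51 ± 0.0529 (SD, n = 2) in shUSP16. The higher genes besides MT2A were RHOXF2 and ESX1, both X-linked homeobox genes, and MYBPC1, a myosin-binding protein gene. MYBPC1 rose from 3.98 FPKM in shControl to 11.4 ± 2.99 (SD, n = 2) in shUSP16 under the limma fit restricted to protein-coding genes (adjusted p = 0.0155).

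Several of these genes have near-identical copies that share reads, so their own values are uncertain. U2AF1, a splicing factor gene, had 1444 reads in shControl, 320 in shUSP16-1 and 366 in shUSP16-2, but summed with its copy U2AF1L5 the ratio to shControl was 0.448 in shUSP16-1 and 0.658 in shUSP16-2. CXorf49 summed with CXorf49B stayed low, at ratios of 0.160 and 0.116. RHOXF2 summed with RHOXF2B had ratios of 1.5 and 1.81, and 12 TBC1D3 family genes together had ratios of 0.559 and 0.539. AC004556.1 lies on a scaffold outside the assembled chromosomes.

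The differences of shUSP16-1 and shUSP16-2 from shControl went together across genes, with a Pearson r of 0.666 across 13852 genes, which are not independent replicates. Simulated unchanged libraries sharing 1 control gave 0.500, and the covariance was 0.0779 against a simulated 0.0397. The size rule met by 79 genes was met by a mean of 56.4 genes in those simulations. The 60 lower genes, 51 of them not protein-coding, lay above the simulated 28.2 (central 95% of simulations 20 to 35.5). The 19 higher genes lay below the simulated 28.2 (21 to 36.5), so there was no excess of higher genes past 2-fold. With no limit of size, 44.9% of genes were higher in both, against a simulated 33.1% (32.4 to 33.9). The share lower in both was 32.4%, against a simulated 33.2% (32.6 to 33.9). Simulated differences centred on 0, while the deposited values had medians of 0.041 in shUSP16-1 and 0.043 in shUSP16-2. With equal totals these medians were -0.0070 and -0.019. Both shares thus depend on the scaling and do not by themselves show an excess of higher genes. Simulated genes varied independently, so these ranges may be too narrow if classes of genes shift together. Independent lists past 2-fold, which leave out the shared control, would share 1.78 lower and 0.310 higher genes. The lone control cannot be split, so part of the excess may come from it; taking shUSP16-1 or shUSP16-2 as the lone library instead gave 48 and 61 genes.

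**Figure D2:**
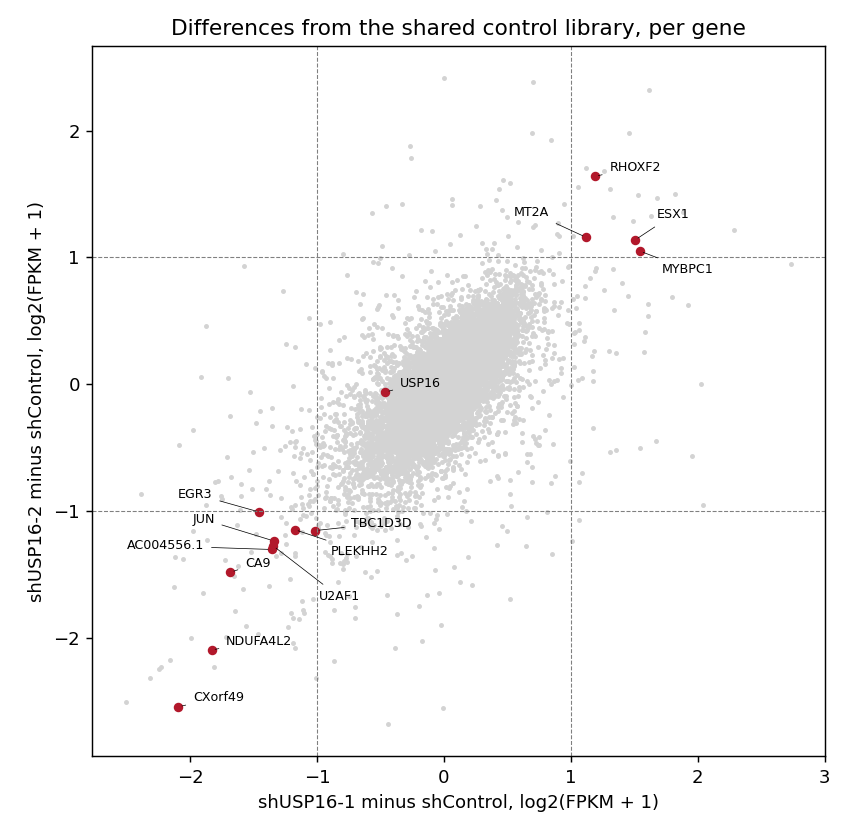
Log2 difference from shControl, on the log2(FPKM + 1) scale, of shUSP16-1 (horizontal axis) and shUSP16-2 (vertical axis) for 13852 genes (grey points), with USP16 and the 13 protein-coding genes at least 2-fold from shControl in both in red; dashed lines mark 2-fold. NDUFA4L2 lies at -1.83 and -2.10, MT2A at 1.12 and 1.16, and USP16 at -0.46 and -0.061.

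Genes of MYC and ribosome biogenesis were higher in both libraries labelled shUSP16 for 51 of 52 tested members, with medians of 0.41 in shUSP16-1 and 0.55 in shUSP16-2 on the log2 scale. DDX21, a nucleolar RNA helicase gene, was at 25.6 FPKM in shControl and 49.2 ± 7.20 (SD, n = 2) in shUSP16, and PES1, needed for 60S subunit maturation, at 14.5 and 24.9 ± 1.06 (SD, n = 2). PNO1 and TFB2M had log2 differences of 0.68 and 0.66. camera with a preset correlation called the list higher (adjusted p = 1.91e-16), and its median exceeded those of all 10000 random lists of equally expressed genes. The call was lost with an estimated correlation (adjusted p = 0.879 with an estimated correlation). That setting rests on 1 residual degree of freedom and was not tried on the simulated data. Losing a call there, for this list or those below, therefore does not show that a list was unchanged. limma called 0 of its members over all genes and 34 adjusted over the list alone; voom called 17 over all genes, and limma restricted to protein-coding genes called 2, both higher. MYC itself, at 114 FPKM in shControl and log2 0.36 higher, was not called (limma adjusted p = 0.292).

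S phase genes were higher in both libraries for 33 of 41 members and lower in both for 0. The medians were 0.17 in shUSP16-1 and 0.44 in shUSP16-2. UNG, a uracil-DNA glycosylase gene, had a log2 difference of 0.75, CDC45, a replicative helicase component, 0.64, and MCM5, a subunit of that helicase, 0.67. camera called the list (adjusted p = 2.02e-06, but adjusted p = 0.879 with an estimated correlation), above all 10000 matched lists; limma called 0 members over all genes and 0 adjusted over the list alone, limma restricted to protein-coding genes called 0, and voom called 4.

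The 40S and 60S ribosomal proteins, nuclear oxidative phosphorylation and G2 and mitosis lists were also called higher by camera (adjusted p = 0.00134, 0.000530, 0.00314 and 0.00302). All 4 calls were lost with an estimated correlation (adjusted p = 0.879 with an estimated correlation), and those of oxidative phosphorylation and G2 and mitosis also with a mean of at least 5 FPKM (adjusted p = 0.0745 and 0.186). Their medians stood only at the 64.8, 28.0, 55.7 and 23.5 percentiles of equally expressed random lists. RPL24 (log2 0.49) and RPS29 (log2 0.63, from 0.36 in shUSP16-1 and 0.89 in shUSP16-2) led upward among ribosomal proteins. RPS10 was at -0.58, from a low level of 4.81 FPKM in shControl. NDUFB9, of respiratory complex I, had a log2 difference of 0.52, and RANGAP1, a Ran GTPase activator gene, 0.53. limma called 0 members of these 4 lists, over all genes or adjusted over the list alone. The unfolded protein and integrated stress response list was called higher (adjusted p = 0.0175), but not with an estimated correlation (adjusted p = 0.879 with an estimated correlation) or a mean of at least 5 FPKM (adjusted p = 0.304). The chaperone gene HYOU1 was at a log2 difference of 0.65 and SDF2L1 at 0.58, but ATF3 at -1.03 and DDIT3 at -0.88, both transcription factor genes induced by stress, went the other way. limma called 0 of its members over all genes and 5 adjusted over the list alone. Restricted to protein-coding genes, limma called 2 of its members, both lower, against the direction of the list. Voom with the authors' totals called 5 members higher and 2 lower. The median of this list stood at the 93.3 percentile of matched random lists.

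Immediate early and dissociation stress genes, which respond within minutes to growth factors and handling, were lower in both libraries for 20 of 26 members and higher in both for 4. The medians were -0.58 in shUSP16-1 and -0.38 in shUSP16-2. Besides JUN and EGR3, ATF3 was at 25.8 FPKM in shControl and 12.1 ± 1.12 (SD, n = 2) in shUSP16, and NR4A1, an orphan nuclear receptor gene, at 17.7 and 8.31 ± 0.590 (SD, n = 2). camera called the list lower (adjusted p = 4.72e-08, but adjusted p = 0.879 with an estimated correlation), below all 10000 matched lists. limma called 0 members over all genes and 12 adjusted over the list alone, while limma restricted to protein-coding genes called 5 lower and 1 higher. The higher one, chosen after its values were seen, was the chaperone gene HSPA8, at 159 FPKM in shControl and 283 ± 27.5 (SD, n = 2) in shUSP16.

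Hypoxia and glycolysis genes were lower in both libraries for 19 of 35 members and higher in both for 9. List medians were only -0.15 in shUSP16-1 and -0.14 in shUSP16-2, much smaller than the differences of the members named here. NDRG1, a hypoxia-induced gene, went from 2.29 FPKM in shControl to 0.599 ± 0.105 (SD, n = 2) in shUSP16, and ADM, encoding adrenomedullin, from 8.91 to 4.23 ± 0.349 (SD, n = 2). PFKFB4, a regulator of glycolysis, had a log2 difference of -0.86. camera called the list lower (adjusted p = 0.000614, but adjusted p = 0.879 with an estimated correlation), below all 10000 matched lists. limma called 0 members over all genes and 8 adjusted over the list alone, and limma restricted to protein-coding genes called 5, all lower.

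Replication-dependent histone genes were lower in both libraries for 11 of 15 members (camera adjusted p = 0.000530, 0.840 percentile, but adjusted p = 0.879 with an estimated correlation), led by HIST1H3H at a log2 difference of -0.80 and HIST1H2AC at -0.83. These 15 were the tested part of 74 listed genes. With a mean of at least 5 FPKM too few members were left to test the list. Many of their transcripts lack a poly(A) tail and how RNA was selected is not given in the sources used here. Interferon response genes were lower in both for 9 of 21 and higher in both for 2, where 32.4% of all tested genes were lower in both. LGALS3BP led at -0.87 (camera adjusted p for the list = 0.0109, 0.680 percentile, but adjusted p = 0.879 with an estimated correlation). limma called 0 members of either list over all genes; adjusted over the list alone it called 1 histone gene and 0 interferon response genes. With an estimated correlation in place of the preset one, camera called 0 of the 26 lists (lowest adjusted p = 0.879 with an estimated correlation), with 1 residual degree of freedom behind that estimate. All 11 lists called at the preset correlation had this same adjusted p, so the setting could not rank them and decides nothing about any one list.

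**Figure D3:**
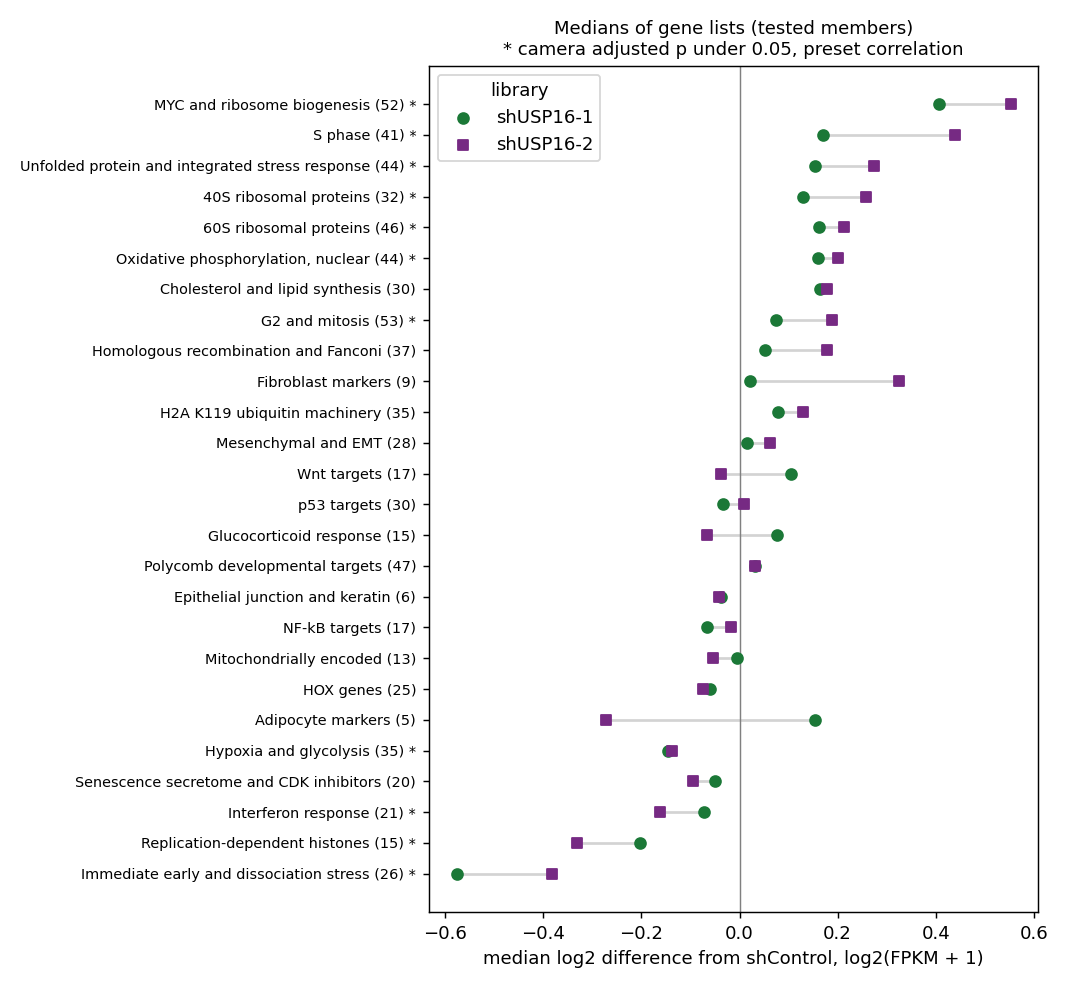
Median log2 difference from shControl, on the log2(FPKM + 1) scale (horizontal axis), of each of the 26 tested gene lists (vertical axis, number of tested members in brackets) in shUSP16-1 (circles) and shUSP16-2 (squares); stars mark lists with a camera adjusted p under 0.05 at the preset correlation. MYC and ribosome biogenesis lies at 0.41 and 0.55, immediate early genes at -0.58 and -0.38.

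The 3 lists tied to H2A ubiquitination and Polycomb were not called by camera. The H2A K119 ubiquitin machinery was higher in both libraries for 24 of 35 members with a median of 0.10 (camera adjusted p = 0.168); BCOR, a Polycomb complex gene, was at 0.38 and PHC3 at -0.32. HOX genes were lower in both for 14 of 25 members with a median of -0.099 (camera adjusted p = 0.122), HOXA5 at -0.51 and HOXA13 at 0.33. The HOX median was smaller in each library alone, at -0.060 in shUSP16-1 and -0.075 in shUSP16-2. Among protein-coding genes alone, camera, run after seeing the data, did call the HOX list lower (adjusted p = 0.0243). Over all genes the list had an adjusted p = 0.879 with an estimated correlation, and its median stood at the 1.80 percentile of matched lists. Polycomb developmental targets were higher in both for 17 and lower in both for 16 of 47 (camera adjusted p = 0.915); MSX2, a homeobox gene, was at 0.96 and WNT6 at -0.59. limma called 0 members of the 3 lists over all genes, and adjusted over the list alone 1 Polycomb target.

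Genes fixed for cell cycle and identity were not called by limma. CCNB1, encoding cyclin B1, had a log2 difference of 0.26, PLK1, a mitotic kinase, 0.20, and MKI67, a proliferation marker, 0.14. CDKN1A, encoding p21, was at -0.17 and CDKN2A, encoding p16, at -0.19. VIM, encoding vimentin, was at 0.12, RPS27A, encoding a ubiquitin fused to a ribosomal protein, at 0.15, and CDH1, encoding E-cadherin, had 0, 2 and 0 reads in shControl, shUSP16-1 and shUSP16-2, too few to test. Their limma adjusted p values ran from 0.370 for CCNB1 to 0.671 for VIM.

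The other lists were not called by camera. Adjusted p was 0.0606 for cholesterol and lipid synthesis, where SQLE was at a log2 difference of 0.48. On voom values camera called that list higher with the authors' totals (adjusted p = 0.0272) but not with sums of reads (adjusted p = 0.0724). On the limma values the list had an adjusted p = 0.879 with an estimated correlation. Adjusted p was 0.122 for homologous recombination and Fanconi, where RBBP8 was at 0.53. It was 0.341 for NF-kB targets, with PTGS2 at -0.59, and 0.614 for p53 targets, with AEN at 0.50 and GADD45A at -0.49. Wnt targets had 0.902 (PROX1 at -0.66, CCND1 at 0.53), mesenchymal and EMT genes 0.915 (S100A4 at 0.83, CYR61 at -1.19), and the senescence list 0.775 (IGFBP5 at 0.46, CDKN1C at -0.33, 11 of 20 lower in both). Epithelial junction genes had 0.614 (TJP3 at -0.39) and mitochondrially encoded genes 0.848 (MT-ND3 at 0.29, MT-ND4 at -0.057, 8 of 13 lower in both). Glucocorticoid response genes had 0.848, with MT2A at 1.14 and MT1X at 0.76 but DUSP1 at -0.82 and ANGPTL4 at -0.82. Medians and camera directions differed in sign for 2 lists, Wnt targets and Polycomb developmental targets. For the senescence, mitochondrially encoded and glucocorticoid lists the mean was above 0 and the median and camera direction below. Against random lists matched on mean expression, the senescence median stood at the 0.01 percentile and that of mitochondrially encoded genes at the 0.04 percentile. For mitochondrially encoded genes the match was poor, since genes such as MT-ND4 (13646 FPKM in shControl) have few equals in expression. Their percentile therefore does not show that they were low for their level. Adjusted over the list alone, limma called 5 glucocorticoid response genes and 1 mesenchymal gene.

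The lists of markers of other cell types were not called by camera. Fibroblast markers were higher in both libraries for 5 of 9 members (camera adjusted p = 0.452), beside the S phase and MYC lists that were also higher. COL1A1, a collagen gene, was at 52.2 FPKM in shControl and a log2 difference of 0.51. COL1A2 was at 0.67, from 0.35 in shUSP16-1 and 0.98 in shUSP16-2, while THY1 was at -0.31. Voom with the authors' totals called COL1A1 (adjusted p = 0.0336) and COL1A2 (adjusted p = 0.0449) higher, and limma called neither. COL3A1, the most expressed of them and chosen after its values were seen, had 192 FPKM in shControl, 173 in shUSP16-1 and 248 in shUSP16-2. Adipocyte markers were mixed (camera adjusted p = 0.848), with DGAT2 at 0.22 and PNPLA2 at -0.16. Too few members reached 1 FPKM to test gastric pit and neck (1 gene), gastric parietal, chief and endocrine (0), endothelial (1) and leukocyte (0) markers.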

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

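Voom, the lone-library counts and camera on protein-coding genes were chosen after seeing the data. limma called 0 genes in the fit fixed beforehand and with a pseudocount of 0.1, no filter, either rescaling, no trend, a robust trend or an adjusted p under 0.1, but 13 with a mean of at least 5 FPKM (3 higher, 10 lower), 48 among protein-coding genes, 348 by voom with the authors' totals and 557 with sums of reads; fewer genes tested and another variance prior (9.81 degrees of freedom for protein-coding genes, 4.05 for all) go with the second of these, and the cause was not tested. The kind of total in voom moved the median of all genes from 0.048 to -0.059 (log2), a shift of -0.11, and the higher calls from 204 of 348 to 139 of 557; 281 genes were called with both. The 79 genes past 2-fold became 241 with a pseudocount of 0.1, 162 with no filter, 20 with a mean of at least 5 FPKM, 13 among protein-coding genes, 412 at 1.5-fold and 14 at 3-fold, and 48 with shUSP16-1 as the lone library; leaving out either library labelled shUSP16 gave 211 to 235. The correlation of 0.666 was 0.609 with a pseudocount of 0.1, 0.621 with no filter, 0.728 with a mean of at least 5 FPKM and 0.731 among protein-coding genes. camera called 11 lists, 7 with a mean of at least 5 FPKM and 0 with an estimated correlation, and 11 to 13 otherwise. With a mean of at least 5 FPKM the replication-dependent histone list, among the 11, had too few members to test. USP16 was lower and not called with a pseudocount of 0.1, either rescaling and voom with either total (adjusted p from 0.202 to 0.570); without shUSP16-1 its value was -0.061 and without shUSP16-2 -0.46, with no test. Equal totals turned the medians of the mesenchymal and EMT list to -0.033 and of Wnt targets to -0.053, TJP1 to -0.036 (-0.080 by voom with sums of reads) and MT-CYB to -0.0090 (-0.051), none of them called. No paired analysis was possible because the control library carries no number and stands alone. Without either library labelled shUSP16 no limma test was run, since no residual degrees of freedom remain. An edgeR test had been planned only for a file of read counts and was not run. limma voom on recovered reads was not part of that plan. Depth limits genes with few reads, such as ESX1 with 26, 150 and 110 reads in shControl, shUSP16-1 and shUSP16-2.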

Other observations

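Every test of an explanation in this part was chosen after the result was seen. The genes named in this paragraph and the next were chosen after their values were seen, with no test of them as groups, and 44.9% of all tested genes were higher in both libraries labelled shUSP16. MSX2, a homeobox gene, was at 19.1 FPKM in shControl and 38.0 ± 1.01 (SD, n = 2) in shUSP16. ID1, ID3 and ID2, encoding inhibitors of helix-loop-helix transcription factors, had log2 differences of 0.72, 0.71 and 0.46, and MSX1 was at -0.0055. Among genes for cytosolic chaperones and their partners, HSPA8 was at 0.82, HSPH1 at 0.69, ST13 at 0.68 and HSP90AA1 at 0.56, while HSPA1A was at -0.39. limma called 0 of these genes over all genes; restricted to protein-coding genes it called MSX2, HSPA8, ID1 and ID3 higher, and voom with the authors' totals called these and HSPH1, ST13 and HSP90AA1.

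Non-coding genes were lower as classes. The median log2 difference was -0.20 for 499 lincRNA genes and -0.18 for 599 antisense genes, against 0.067 for 11069 protein-coding and 0.054 for 553 processed pseudogenes; antisense genes cannot be told from their partners if reads were counted without strand. NEAT1, the scaffold RNA of nuclear paraspeckles, went from 55.4 FPKM in shControl to 38.2 in shUSP16-1 and 29.1 in shUSP16-2, and MIR210HG, the host gene of a hypoxia-induced microRNA, from 7.23 to 2.64 and 2.22. MALAT1, another nuclear RNA, had 33.2, 31.6 and 29.1 FPKM. Mitochondrial ribosomal RNA took 2.26% of reads in shControl, 1.62% in shUSP16-1 and 1.57% in shUSP16-2.

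The lower level of immediate early genes could in principle come from scaling, from USP16 or from the state of the lone control culture. One factor per library would move all genes alike, yet the median of this list, fixed before the data were examined, lay -0.51 from that of all tested genes (bootstrap 95% interval -0.63 to -0.41 over members, which are not independent); this value, already seen through the list test, argues against such a factor as the whole cause. If the change followed USP16 mRNA, it would be small in shUSP16-2, but the ratio of list medians between shUSP16-2 and shUSP16-1 exceeded that of USP16 by 0.530 (0.243 to 0.914), or by 0.423 (0.163 to 0.775) with sums of reads. A first version of this test, a fixed limit of 0.3 on the ratio of list medians (0.663, 0.454 to 0.997), came out against the explanation and was rewritten after that result because it left out the counting error of USP16; since each level of USP16 rests on 1 library, which this design cannot change, the explanation is left open. With 1 control library, an effect of USP16 and a control culture that was more stressed, denser or lower in oxygen when harvested cannot be told apart, and both stay open.

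The higher level of MYC and ribosome biogenesis genes may be read the same way. Its median lay 0.43 above that of all tested genes (0.39 to 0.49), a value already seen through the list test, which argues against a single factor per library as the whole cause. The ratio of list medians exceeded that of USP16 by 1.22 (0.996 to 1.55), and by 1.07 (0.845 to 1.38) with sums of reads; the list was further from shControl in shUSP16-2, the library with more USP16 mRNA, and the first version of the test came out against the explanation here too (ratio 1.36, 1.24 to 1.57), but 1 library per level leaves it open. The state of the 1 control culture and an effect of USP16 remain open and cannot be told apart.

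The lower level of non-coding genes might come from less genomic DNA in the libraries labelled shUSP16, or from a bias with gene length and depth. Reads in 406 olfactory receptor genes, taken as a gauge of genomic DNA, went from 455 in shControl to 358 and 372, and this drop per kilobase would give 1.91% (0.418 to 3.40) of the drop in lincRNA and antisense reads, which argues against genomic DNA as the whole cause. Set against the 20 protein-coding genes nearest in length and mean reads, 1098 lincRNA and antisense genes were still lower, with a median of -0.089. The bootstrap 95% interval over genes, which are not independent, was -0.11 to -0.064 and does not cover the spread between libraries. The remaining gap argues against length and depth as the whole cause. Matching took the gap from -0.25 to 34.9% of that size, so most of it went with length and depth. RNA quality, nuclear RNA yield and an effect of USP16 were not tested and stay open.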
